A study of Daphnia magna with 144 samples.

How the data were processed

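Gene expression was measured in *Daphnia magna*, a freshwater water flea, on 1-colour arrays labelled with Cy3. Per the labels, groups of 20 animals aged 14 days were kept for 24 h in 1 L of medium that held a chemical at 1/10 of its LC50, the concentration lethal to the median animal. The 144 arrays cover 36 chemicals with 4 replicates each. The labels name a vehicle control for every chemical, and 13 chemicals fall to Media, 15 to Ethanol, 3 to Methanol, 3 to Acetone and 2 to DMSO. Replicates of different chemicals share only a number, so no samples were paired. Neither a slide nor a scan date is given, and the 4 arrays of a chemical may share handling in full or in part, so chemical and batch cannot be told apart. The p-values therefore measure the spread between these samples.

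Both deposited forms of the data were used. The scanner tables hold the median foreground and the median local background intensity at every spot, per the file headers, without normalization by the authors. The deposited value table holds a log2 ratio of each array to a reference that belongs to the vehicle. The labels name limma among the authors' tools and give no further settings. The meaning of the value table was checked against the scanner tables. Among the scanner columns of its own chemical, each of the 144 value columns was matched best by the one with the same array number. Both were centred on the mean of the chemical's arrays, and their correlation across probes was 0.781 at the lowest and 0.906 at the median. Scanner columns of other chemicals were not candidates, so this match tests the order of the arrays and does not by itself test the chemical. For 190 pairs of chemicals with the same vehicle and 6676 bright probes, differences between value columns had a median slope of 0.981 on differences between scanner columns, with a range from 0.913 to 1.04. The reference implied by subtracting a value from its scanner log2 signal was nearly the same for chemicals of a vehicle, with a median correlation of 0.997, and less so across vehicles, with a median of 0.9. The scanner columns were tied to the samples by the chemical in the table name and the array number. The 20 control arrays in 5 further tables match no sample of the series and were not used here, so the spread of the controls themselves is left out of every ratio.

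Each array has 15744 spots, of which 536 are control spots. The scanner tables hold 14338 probes, 870 of them spotted 2 times. Scanner values were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, put on the log2 scale and averaged over duplicate spots. The 116 probes with a bad-spot flag on any array were dropped, which left 14222. The values were then quantile normalized over all arrays. The offset compresses the fold of dim probes. The value table holds 13481 probes, all found in the scanner tables, and 857 probes of the scanner tables are not in it. A probe counted as above background where foreground minus background exceeded the mean plus 3 SD of 77 negative control spots of the array. A fold whose lower side was above background on no array, or whose higher side was at the scanner limit of 65535, is a lower bound. An implied reference counted as at that limit from a log2 signal of 15.62, the lowest of a probe saturated on all 4 arrays of a chemical. No bound was set above the fold of the mean values or, for ratios and pairs, above the fold with any replicate left out. The median foreground of an array ranged from 67 to 125 and the median background from 35 to 41. The share of probes above background ranged from 52.3% to 95.2%, with a median of 81.7%, and 1 to 29 probes per array were saturated. The number of arrays limits the precision.

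The comparisons, their tests, most of the alternatives and the rule for naming probes were fixed before the data were examined. The alternatives and tests that were added later are named in the closing section. A single limma model with 36 group means over the 144 arrays, with 108 residual degrees of freedom, gave a moderated test per probe. The p-values were adjusted by the Benjamini-Hochberg method within each contrast and a probe was called at an adjusted p under 0.05. The deposited log2 ratios were used for each chemical against its vehicle control (the mean of 4 ratios against 0) and for pairs of chemicals with different vehicles. The scanner log2 values were used for each chemical against the equally weighted mean of the other chemicals of its vehicle, for pairs with the same vehicle, for metals and metalloids against the other chemicals in medium (limma on 13 chemical means) and for the classification of arrays. Classification used the nearest group mean by Pearson correlation. Arrays were assigned to a chemical with each replicate number left out in turn, after centring within the vehicle, and compared with 1000 permutations of the labels within vehicles. Chemicals in medium were assigned to metal or not with each chemical left out in turn, and compared with all 715 splits. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures.

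No source used here pairs the probes with gene names: 0 of the probe names were found in the reference table of 28335 genes. The gene list tests and the cell type marker tests that had been planned were therefore not run, and probes are named by their identifiers. Described in depth are the 3 chemicals with the most calls against the control in Media and in Ethanol and the 1 with the most in Methanol and in Acetone. For each of these and each pair, the 2 probes with the largest change in each direction are named, among called probes with all 4 arrays on the same side of the comparison value.

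The pipeline was tested on simulated data with known changes. The simulated ratios held no error of the shared control arrays, so false calls that such an error can cause against the control could not show. Changes of 1 on the log2 scale were recovered in 89.6% of probes against the control, in 98.5% for the pair Bifenthrin and Lamda Cyhalothrin and in 83.6% for metals against other chemicals. Changes of 0.5 were recovered in 67.2%, 88.1% and 35.8%. The alternatives were another deposited form of the values, median centring, quantile normalization of the ratios, a filter on dim probes, a fit on fewer arrays, a replicate block, a variance trend, a minimum change of 1 on the log2 scale, and leaving out replicates. The closing section gives their effect.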

Results

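The series holds arrays of whole *Daphnia magna*, 4 for each of 36 chemicals. The chemicals were 9 metals or metalloids, pesticides, hormones and their analogs, solvents and other organic compounds. The title of the series states that exposure is to be predicted from expression. The median foreground of the arrays ran from 67 to 125 over a background of 35 to 41. Unless another number is given, n = 4 arrays, errors are SD and adjusted p-values are from limma. Except for metals, the p-values use a spread pooled over the arrays of all 36 chemicals. A probe with a large SD in its own 4 arrays can therefore still have a very small p.

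Against the vehicle control, in the deposited log2 ratios, some of the 13481 probes were called in every one of the 36 chemicals. The error of the control arrays is not in this test, so the p-values are too small and the counts can be too high. The number of called probes ran from 3000 for 2-chloro vinyl ether and 3636 for Toluene to 10562 for Phenol and 10764 for 20 hydroxyecdysone, the arthropod moulting hormone. The sum over the 36 chemicals was 293167 calls, of which 85492 had a change of at least 1 on the log2 scale. With quantile normalization of the ratios, the range narrowed to between 7763 for Methylfarnesoate and 8643 for Manganese. It gave 7824 for 2-chloro vinyl ether, 7815 for Toluene and 8476 for 20 hydroxyecdysone. This scaling gives every array the same distribution of ratios, where their SD had run from 0.43 to 1.58 over the arrays. It narrows the range by construction and does not test the order of the chemicals. Median centring of the ratios gave 10764 for 20 hydroxyecdysone, 10550 for Phenol and a sum of 293105. The count for 2-chloro vinyl ether fell to 1981 without replicate 1 of all chemicals. Ratios of chemicals with the same control covaried across probes. The mean over the chemicals of a vehicle held 71.8% of the squared ratio in Media and 48.7% in Ethanol. It held 83.2% in Acetone, 59.1% in DMSO and 54.5% in Methanol, where 2 or 3 chemicals make such a share large by construction. The median covariance was 0.89 in Media, 0.735 in Acetone, 0.279 in Ethanol, 0.194 in DMSO and 0.101 in Methanol, where simulated unchanged chemicals with a shared control gave 0.0402, 0.0418, 0.0402, 0.0425 and 0.0404. In the same order, the median correlations were 0.721, 0.773, 0.491, 0.234 and 0.285, and those of the simulated chemicals 0.499, 0.506, 0.499, 0.516 and 0.497. By correlation, only Media and Acetone exceeded the simulation, while by covariance all 5 vehicles did. The simulated correlation is set by the numbers of treated and control arrays, and changes particular to a chemical lower a correlation. A correlation under the simulated one therefore does not show that sampling noise explains the shared ratios. In Media, 1084 probes were called higher and 1035 lower in all 13 chemicals. The 440 pairs of chemicals with different vehicles had correlations from -0.603 to 0.679, with a median of 0.004, and probes are not independent replicates.

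**Figure D1:**
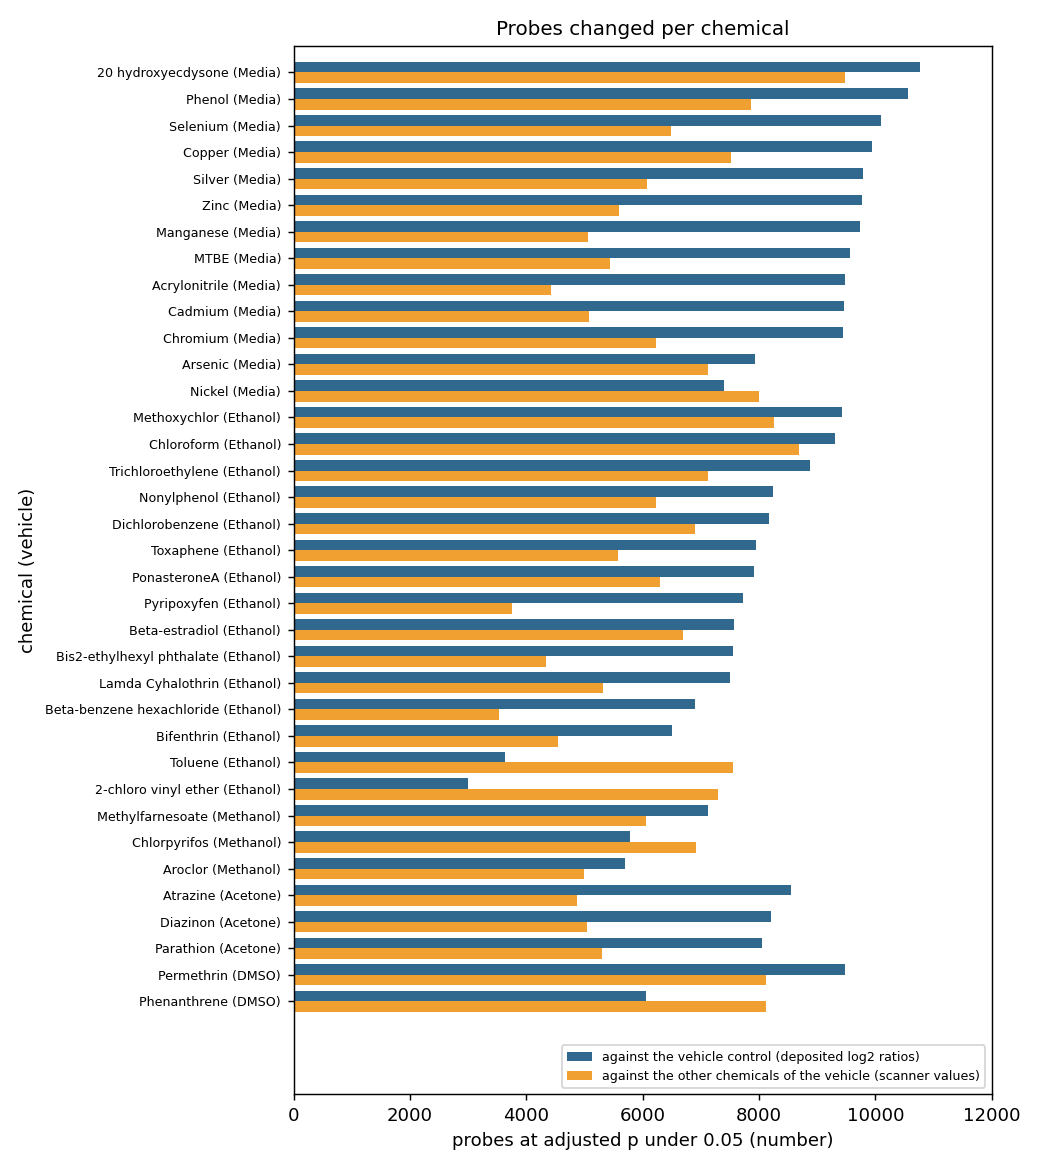
Number of probes at an adjusted p under 0.05 (horizontal axis) for each of 36 chemicals (vertical axis, vehicle in brackets), against the vehicle control in the deposited log2 ratios and against the other chemicals of the vehicle in the scanner values. The counts against the control run from 3000 for 2-chloro vinyl ether to 10764 for 20 hydroxyecdysone.

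In animals exposed to 20 hydroxyecdysone, 5399 probes rose and 5365 fell against the Media control. DM04369 rose by a log2 ratio of 14.10 ± 0.26 (adjusted p = 4e-41) and DM02775 by 12.58 ± 0.23 (adjusted p = 5e-36), at least 4302-fold since its 4 arrays were saturated. The implied Media reference of DM04369, 2.43, lies near the lowest detected signal of these arrays, 1.30, so the size of its ratio is uncertain. DM01737 had a log2 ratio of -8.03 ± 0.18 (adjusted p = 3.3e-90), above background on 3 of 4 arrays. DM07102 had one of -9.18 ± 2.55 (adjusted p = 2.3e-43), above background on 1 of 4 arrays and between -10.13 and -8.41 with a replicate left out. The named probes were not all particular to this chemical. DM04369 and DM02775 rose in 13 of 13 Media chemicals, DM01737 fell in 11 and DM07102 in 6. With a change of at least 1 on the log2 scale required, 5579 probes were called.

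In Phenol, 5284 probes were called higher and 5278 lower than the Media control. DM02775 (12.48 ± 0.22, adjusted p = 1.5e-35) and DM02924 (11.03 ± 0.21, adjusted p = 2.7e-27) rose the most, at least 4683-fold and at least 1847-fold, with all 4 arrays saturated. The implied Media reference of DM02775, 3.69, lies near the lowest detected signal of these arrays, 2.77, so the size of its ratio is uncertain. DM05687 had a log2 ratio of -7.23 ± 0.18 (adjusted p = 2.3e-39), above background on 3 of 4 arrays. DM05344 had one of -8.15 ± 1.64 (adjusted p = 6.1e-31), at least 31.7-fold lower as it was above background on 0 of 4 arrays. Without replicate 1, DM05344 had -8.77. DM02775 and DM02924 rose in 13 of 13 Media chemicals, DM05687 fell in 12 and DM05344 in 7. A minimum change of 1 on the log2 scale left 4995 probes.

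In Selenium, 5081 probes were called higher and 5017 lower than the Media control. DM02775 rose by 10.57 ± 0.47 (adjusted p = 8.2e-30) and DM11495 by 8.67 ± 0.15 (adjusted p = 3e-77), a 408-fold change. For DM02775 the implied reference, 3.69, lies near the lowest detected signal of these arrays, 2.38, so the size of its ratio is uncertain. DM08350 had a log2 ratio of -8.71 ± 0.09 (adjusted p = 4.4e-79) and DM01737 of -8.47 ± 0.21 (adjusted p = 1e-92), each above background on 3 of 4 arrays. DM02775, DM11495 and DM08350 moved the same way in 13 of 13 Media chemicals. At least 1 log2 unit of change was reached by 4415 called probes.

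Among the Ethanol chemicals, Methoxychlor, an organochlorine insecticide, had 4522 probes called higher and 4906 lower than the Ethanol control. DM09934 rose by 5.48 ± 0.07 (adjusted p = 3.3e-11) and DM12319 by 5.40 ± 0.24 (adjusted p = 7.8e-11), at least 22.1-fold. DM11146 had a log2 ratio of -9.26 ± 0.63 (adjusted p = 2.3e-55), at least 439-fold lower with 0 of 4 arrays above background, and DM00608 of -9.08 ± 2.40 (adjusted p = 3.1e-26), from -9.79 to -8.37 with a replicate left out. DM00608 stood at -6.96 and -7.05 in replicates 1 and 2 and at -11.23 and -11.10 in replicates 3 and 4. Its implied reference, 15.93, is as bright as saturated probes, so its mean was at least 330-fold lower. DM09934 rose in 7 and DM11146 fell in 10 of the 15 Ethanol chemicals. Of the called probes, 3153 changed by at least 1 on the log2 scale.

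In Chloroform, 4385 probes were called higher and 4916 lower than the Ethanol control. DM09934 rose by 6.78 ± 0.10 (adjusted p = 4.9e-15), a 110-fold change, and DM07636 by 5.46 ± 0.24 (adjusted p = 4.4e-16). For DM07636 the implied reference, 3.05, lies near the lowest detected signal of these arrays, 1.99, so the size of its ratio is uncertain. DM11495 had a log2 ratio of -8.52 ± 0.14 (adjusted p = 3.5e-75) and DM04369 of -8.11 ± 0.36 (adjusted p = 3.6e-22). DM11495 fell in 14 of the 15 Ethanol chemicals and DM04369 in 8. With a minimum change of 1 on the log2 scale, 2803 probes were called.

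In Trichloroethylene, 4620 probes were called higher and 4265 lower than the Ethanol control. DM08350 rose by 7.40 ± 0.18 (adjusted p = 4.9e-71), a 169-fold change, and DM12319 by 6.29 ± 0.22 (adjusted p = 2.5e-13), at least 74-fold. DM04369 had a log2 ratio of -11.71 ± 0.81 (adjusted p = 1.5e-33), above background on 3 of 4 arrays. DM02924 had one of -8.69 ± 0.13 (adjusted p = 5e-20), at least 379-fold lower as its implied reference of 15.98 is as bright as saturated probes. DM08350 rose in 7 and DM04369 fell in 8 of the 15 Ethanol chemicals. A minimum change of 1 on the log2 scale left 2511 probes.

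Methylfarnesoate, a crustacean juvenoid hormone, had 3378 probes called higher and 3753 lower than the Methanol control. DM08360 rose by 10.31 ± 0.13 (adjusted p = 1.2e-57) and DM08350 by 7.87 ± 0.22 (adjusted p = 1.9e-74), 1269-fold and 234-fold. The implied Methanol reference of DM08360, 2.77, lies near the lowest detected signal of these arrays, 2.26, so the size of its ratio is uncertain. DM07835 had a log2 ratio of -7.69 ± 1.04 (adjusted p = 8.1e-55), above background on 1 of 4 arrays, and DM04057 of -7.63 ± 0.25 (adjusted p = 1.6e-62). DM07835 and DM04057 fell in 3 of 3 Methanol chemicals, and DM08360 and DM08350 rose in 2. At least 1 log2 unit of change was reached by 1850 called probes.

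Atrazine, a triazine herbicide, had 4246 probes called higher and 4299 lower than the Acetone control. DM08360 rose by 10.09 ± 0.24 (adjusted p = 4.1e-57) and DM08350 by 9.62 ± 0.27 (adjusted p = 1.6e-83). Their implied Acetone references, 3.48 and 3.13, lie near the lowest detected signal of these arrays, 2.67, so the size of both ratios is uncertain. DM07698 had a log2 ratio of -9.20 ± 0.32 (adjusted p = 4.9e-34), above background on 2 of 4 arrays, and DM11495 of -8.22 ± 0.02 (adjusted p = 6.1e-75). DM08360, DM08350 and DM11495 moved the same way in 3 of 3 Acetone chemicals. Of the called probes, 2300 changed by at least 1 on the log2 scale.

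**Figure D2:**
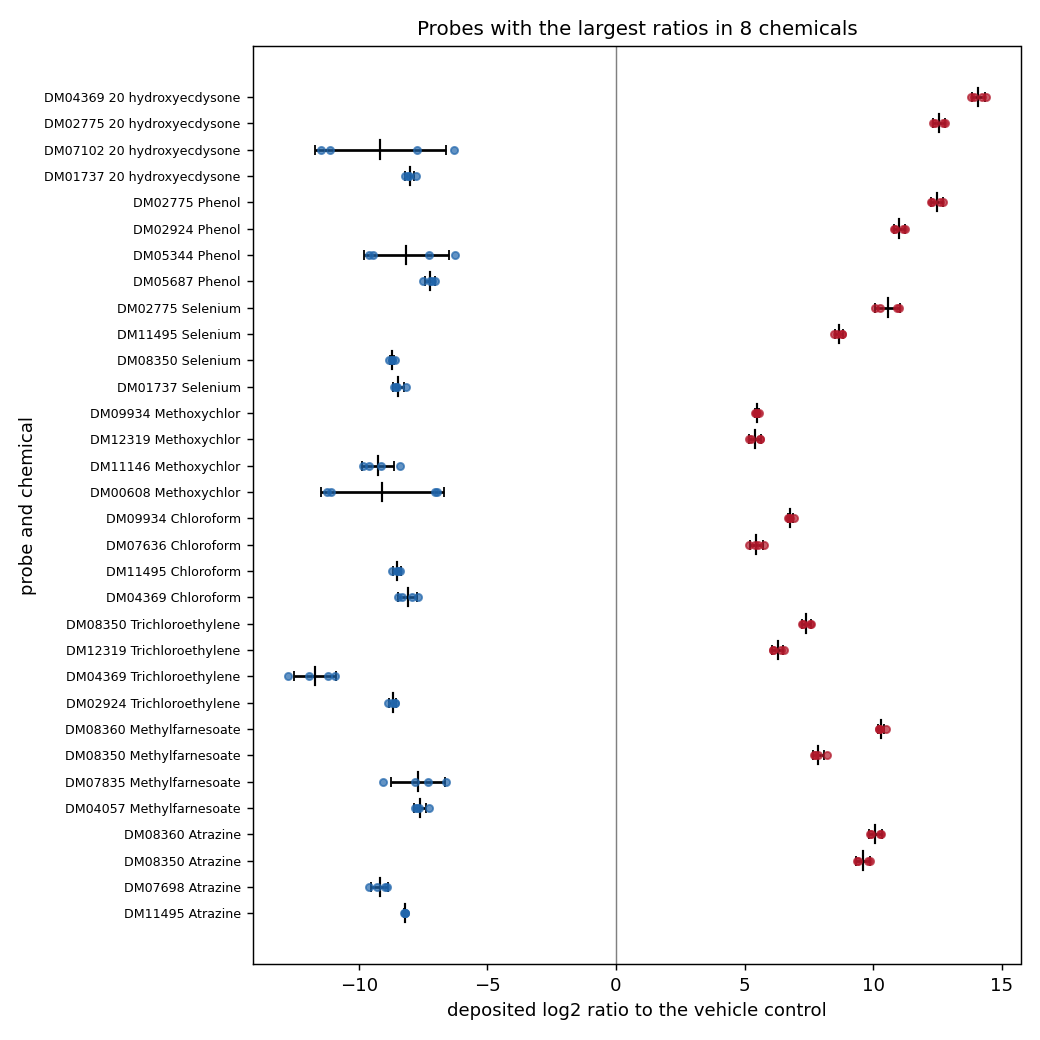
Deposited log2 ratio to the vehicle control (horizontal axis) of the named probes in 8 chemicals (vertical axis), with a point per array, a vertical line at the mean and a bar of 1 SD to each side (n = 4). All 4 points of a probe lie on the same side of 0, from DM04369 at 14.10 in 20 hydroxyecdysone to DM04369 at -11.71 in Trichloroethylene.

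Against the other chemicals of the vehicle, in the scanner log2 values, what sets a chemical apart was asked without a control array. The p-values rest on the spread among arrays of the same chemical and not on the SD between the other chemicals. A small p therefore does not mean that a probe is particular to a chemical. DM11495, for example, had the largest positive difference in both Phenol and Selenium, with log2 values of 14.37 and 14.44. The counts over 14222 probes ran from 3524 for Beta-benzene hexachloride to 9481 for 20 hydroxyecdysone, and their sum was 225853. Of these calls, 17231 had a change of at least 1 on the log2 scale. Permethrin and Phenanthrene are the only chemicals in DMSO, so their 8120 calls are a single contrast. Median centring in place of quantile normalization moved the median of all probes by at most 0.11 on the log2 scale. That is not small here, since the median absolute difference ran from 0.067 for Beta-benzene hexachloride to 0.207 for 20 hydroxyecdysone. With median centring, the share of calls that were higher moved from 47.5% to 67.5% in Nonylphenol and from 47.5% to 28.3% in 2-chloro vinyl ether. The balance of directions therefore depends on the scaling in some chemicals.

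In 20 hydroxyecdysone, 5077 probes were higher and 4404 lower than in the other 12 Media chemicals. DM04369 stood at 15.38 ± 0.12 against 7.36 ± 0.96 (SD over 12 chemical means), 261-fold higher (adjusted p = 3.8e-30), and DM06504 at 13.24 ± 0.58 against 8.18 ± 1.23 (adjusted p = 9.8e-22). DM09934 stood at 6.83 ± 0.06 against 12.79 ± 1.60 (adjusted p = 2.1e-12) and DM05761 at 6.36 ± 0.04 against 11.95 ± 1.06 (adjusted p = 4.6e-43). With a minimum change of 1 on the log2 scale, 1148 probes were called.

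Phenol had 3674 probes higher and 4190 lower than the other Media chemicals, with 489 changed by at least 1 on the log2 scale. DM11495 stood at 14.37 ± 0.18 against 9.66 ± 2.96 (adjusted p = 1e-57) and DM11692 at 6.86 ± 0.03 against 11.26 ± 2.11 (adjusted p = 2.1e-22). DM04057 differed by 3.63 and DM06262 by -3.63 (adjusted p = 3e-38 and 1.6e-11). Selenium had 3903 higher and 2585 lower, with 472 changed by at least 1. The share of its calls that were higher was 60.2%, and 48.9% with the deposited log2 ratios in place of the scanner values. DM11495 was 27.5-fold and DM11208 15.4-fold higher in Selenium (adjusted p = 3e-59 and 5.2e-73), while DM12463 differed by -4.85 and DM08856 by -4.61 (adjusted p = 4.4e-72 and 8.8e-65). Selenium had 10098 calls against the control and 6488 here.

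Methoxychlor had 4144 probes higher and 4117 lower than the other 14 Ethanol chemicals, with 739 changed by at least 1 on the log2 scale. The share that was higher, 50.2%, was 65.7% with median centring. DM08004 stood at 7.38 ± 0.12 against 13.96 ± 1.29 (adjusted p = 1.3e-66) and DM07982 at 6.88 ± 0.06 against 13.44 ± 1.46 (adjusted p = 5.8e-44). DM04714 was 10.6-fold and DM06490 9.84-fold higher in Methoxychlor (adjusted p = 3.7e-48 and 4.3e-41). Chloroform had 4526 higher and 4154 lower, with 885 changed by at least 1. DM09934 rose to 14.87 ± 0.05 against 10.67 ± 2.65 (adjusted p = 1.9e-07) and DM08009 to 13.72 ± 0.95 against 9.83 ± 1.77 (adjusted p = 1e-54). DM04369 differed by -4.46 and DM06182 by -3.68 in Chloroform (adjusted p = 1.7e-14 and 5.5e-15). The difference of DM06182 was -3.07 and -3.09 without replicates 1 and 2, and -4.27 and -4.30 without replicates 3 and 4. Trichloroethylene had 3674 higher and 3454 lower, with 464 changed by at least 1. DM08350 was 64.1-fold and DM07427 39.6-fold higher (adjusted p = 1.5e-66 and 1.1e-58), while DM04369 stood at 6.09 ± 0.15 against 11.99 ± 3.49 and DM14198 at 6.73 ± 0.11 against 12.11 ± 1.28 (adjusted p = 1.7e-20 and 4.1e-11).

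Methylfarnesoate had 2230 probes higher and 3826 lower than Aroclor and Chlorpyrifos, the other 2 Methanol chemicals, with 607 changed by at least 1 on the log2 scale. The share that was higher, 36.8%, was 50% in the deposited log2 ratios. DM09557 stood at 14.27 ± 0.11 against 7.10 ± 0.20 (adjusted p = 1e-53), 145-fold higher, and DM06490 at 14.68 ± 0.07 against 7.90 ± 0.41 (adjusted p = 1.6e-63). DM07698 differed by -5.41 and DM06262 by -4.46 (adjusted p = 7e-15 and 3.5e-12). Atrazine had 2214 higher and 2660 lower than Diazinon and Parathion, with 234 changed by at least 1. Median centring gave 10009 calls in place of 4874 and moved the share that was higher from 45.4% to 56.8%, and Atrazine had 8545 calls against the control. DM01611 was 21.3-fold higher in Atrazine (adjusted p = 1.1e-39) and DM04369 stood at 9.97 ± 2.50 against 6.76 ± 0.35 (adjusted p = 2.1e-06), a difference of 3.21. That difference was 2.32 and 2.37 without replicates 1 and 4, and 3.98 and 4.17 without replicates 2 and 3, so it rested mostly on replicates 1 and 4. DM06371 differed by -2.84 (adjusted p = 1.4e-19) and DM07698 by -3.13 (adjusted p = 2.4e-06), where Diazinon stood at 6.22 and Parathion at 12.27. In Atrazine, DM07698 was above background on 2 of 4 arrays.

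**Figure D3:**
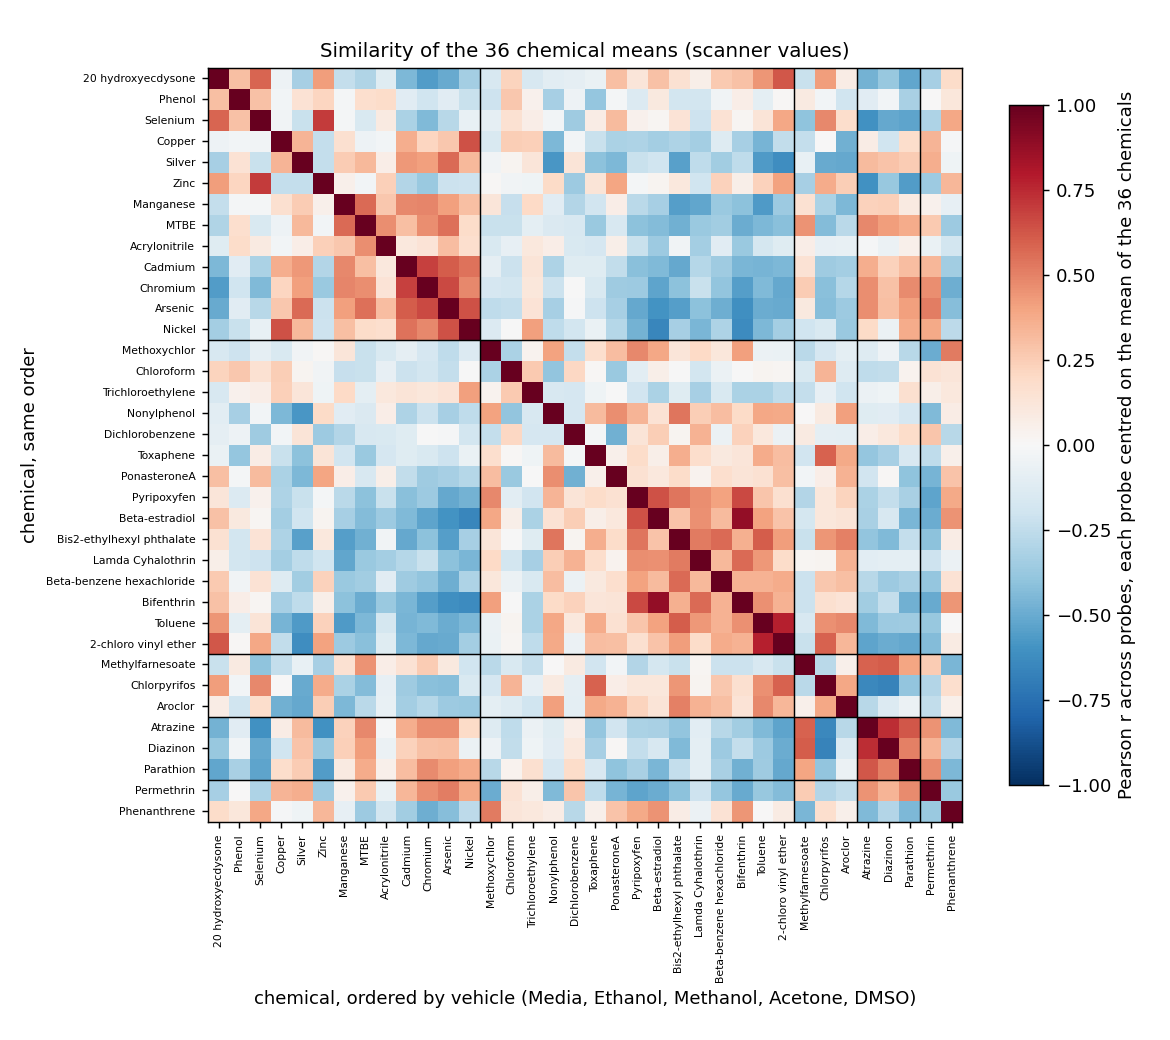
Pearson correlation across probes (colour scale) between the means of 36 chemicals (both axes, ordered by vehicle, black lines between vehicles), from scanner log2 values with each probe centred on the mean of the 36 chemicals. The pair Beta-estradiol and Bifenthrin stands at 0.875.

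Related compounds were compared pair by pair, and the doses differ within every pair. In the order of the pairs below, 243 of 3922, 728 of 5372, 673 of 7059, 6948 of 10498 and 2903 of 7603 calls had a change of at least 1 on the log2 scale. Bifenthrin (0.0001 mg/L) and Lamda Cyhalothrin (0.0006 mg/L) are pyrethroid insecticides, of which the former lacks the cyano group. In the scanner values, 1977 probes were higher and 1945 lower in Bifenthrin. DM04057 stood at 14.20 ± 0.04 against 6.60 ± 0.02 (adjusted p = 1.1e-55), 195-fold higher, and DM11644 at 14.19 ± 0.05 against 7.38 ± 0.05 (adjusted p = 9.3e-82). DM08360 stood at 6.41 ± 0.07 against 11.40 ± 0.07 (adjusted p = 2.7e-28) and DM07027 at 9.16 ± 0.07 against 12.52 ± 0.02 (adjusted p = 5.2e-18). Against the Ethanol control, 1877 probes rose and 2299 fell in both, and their ratios correlated across probes at 0.694. The covariance of their ratios was 0.321, against 0.0402 in simulated unchanged chemicals that share only the sampling noise of a control. By correlation, those simulated chemicals gave 0.499. The 105 pairs of Ethanol chemicals had a median of 0.491 and a highest value of 0.849. Their scanner values correlated at 0.233 when centred on the vehicle and at 0.565 when centred on all 36 chemicals. Median centring gave 1669 calls with 37.7% higher in place of 3922 with 50.4%, and a fit on the 8 arrays alone gave 6362.

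Diazinon (0.0003 mg/L) and Parathion (0.00226 mg/L) are organophosphate insecticides. In the scanner values, 2644 probes were higher and 2728 lower in Diazinon. DM05279 stood at 11.03 ± 0.32 against 7.54 ± 0.20 (adjusted p = 2.8e-38) and DM10454 at 13.27 ± 0.23 against 9.98 ± 0.21 (adjusted p = 1.3e-12). DM07698 stood at 6.22 ± 0.02 against 12.27 ± 0.80 (adjusted p = 4.7e-14), and DM05972 was at least 37.7-fold lower in Diazinon, with 0 of 4 arrays above background (adjusted p = 6e-39). Against the Acetone control, 2733 probes rose and 2203 fell in both, and their ratios correlated across probes at 0.693, the lowest of the 3 Acetone pairs. The covariance of their ratios was 0.663. Simulated unchanged chemicals with only the sampling noise of a shared control gave a covariance of 0.0418 and a correlation of 0.506. Their scanner values correlated at -0.717 when centred on the 3 Acetone chemicals, which by itself lowers a correlation, and at 0.503 when centred on all 36, so the sign depends on the centring.

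Chloroform (7.47 mg/L) and Trichloroethylene (2.49 mg/L) are small chlorinated hydrocarbons. In the scanner values, 3573 probes were higher and 3486 lower in Chloroform. DM14198 stood at 13.13 ± 0.41 against 6.73 ± 0.11 (adjusted p = 5.3e-09), 84.1-fold higher, and DM04057 at 11.99 ± 1.51 against 6.73 ± 0.07 (adjusted p = 3e-40). DM08350 stood at 7.78 ± 0.69 against 12.96 ± 0.23 (adjusted p = 2e-46) and DM06182 at 8.93 ± 2.12 against 13.61 ± 0.49 (adjusted p = 4.5e-13). Without a replicate, the difference of -4.68 for DM06182 ran from -5.43 to -3.94. Against the Ethanol control, 2683 probes rose and 2855 fell in both, and their ratios correlated across probes at 0.643. The covariance of their ratios was 0.532, against 0.0402 in simulated unchanged chemicals with only the sampling noise of a shared control. By correlation, those simulated chemicals gave 0.499, and the 105 pairs of Ethanol chemicals ranged up to 0.849 with a median of 0.491. Their scanner values correlated at 0.402 when centred on the vehicle and at 0.260 when centred on all 36 chemicals.

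20 hydroxyecdysone (1.37 mg/L, Media) and PonasteroneA (0.813 µM, Ethanol) are ecdysteroids, and the latter lacks a side-chain hydroxyl group. In the deposited ratios to their own controls, 5364 probes were higher and 5134 lower in 20 hydroxyecdysone. Against their own controls, 879 probes were higher and 873 lower in both compounds, fewer than the 1563.1 and 1597.8 of independent calls. In opposite directions moved 4897 probes, against 3161.2 of independent calls. DM04369 had ratios of 14.10 ± 0.26 and -8.17 ± 0.28 (adjusted p = 5.2e-45), and DM02924 of 11.13 ± 0.22 and -5.85 ± 0.10 (adjusted p = 5.4e-30), the latter at least 95992-fold apart, since its 4 arrays of 20 hydroxyecdysone were saturated and its Ethanol reference of 15.98 is as bright as saturated probes. DM07380 was at least 240-fold lower in 20 hydroxyecdysone (adjusted p = 8.1e-46), and DM01737 had ratios of -8.03 ± 0.18 and 3.01 ± 0.14 (adjusted p = 7e-89). The vehicles differ, and so do the implied references: for DM04369 the signals were 15.31 and 6.79 over references of 2.43 and 14.91. Each reference is a mean over all arrays of the vehicle, so signal minus reference differs from the printed ratio. Over so dim a Media reference, the size of the ratio of 14.10 is uncertain. Across probes, the ratios correlated at -0.298, but the scanner values centred on all 36 chemicals at 0.300. These correlations differ in the form of the data, the normalization and the centring as well as in the control, so the cause of the change of sign was not tested.

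Methylfarnesoate (labelled 20 with the units nM and mg/L, Methanol) and Pyripoxyfen (0.3 nM, Ethanol), a synthetic insecticide, are juvenoids. In the deposited ratios, 3845 probes were higher and 3758 lower in Methylfarnesoate. DM08360 had ratios of 10.31 ± 0.13 and -2.22 ± 0.07 (adjusted p = 8.8e-51), and DM11495 of 0.36 ± 0.18 and -8.65 ± 0.03 (adjusted p = 6.3e-63). The implied Methanol reference of DM08360, 2.77, is dim, so the size of its ratio of 10.31 is uncertain. DM07698 had ratios of -7.00 ± 0.41 and 6.49 ± 0.05 (adjusted p = 9e-35), and DM05344 of -3.27 ± 1.81 and 8.91 ± 0.03 (adjusted p = 6.6e-32). DM05344 was above background on 0 of 4 Methylfarnesoate arrays and at least 2466-fold lower there, a bound taken without replicate 2, which had -5.98 where the others had -2.58 to -2.24. Against their own controls, 1260 probes were higher and 1212 lower in both compounds, where independent calls would give 965.5 and 1079.6. The ratios correlated across probes at 0.107, and the scanner values centred on all 36 chemicals at -0.292. In the scanner values, 40.1% of the calls were higher in place of 50.6%. The vehicles differ, so each value rests on its own control, and a probe that was not called in any of these 5 pairs is not shown to respond alike.

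The 9 metals or metalloids were compared with 20 hydroxyecdysone, Acrylonitrile, MTBE and Phenol, each chemical counted as a replicate. At the adjusted threshold, limma called 0 probes, with a smallest adjusted p of 0.11. At an unadjusted p under 0.05 there were 1892 probes, where 711.1 are given by chance. In the deposited ratios limma also called 0. Leaving out replicate 3 of all chemicals gave 2 calls, leaving out Acrylonitrile replicate 1 gave 4 and treating the chemical as a random block over arrays gave 573 together with a replicate block and 616 without one.

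By nearest group mean, all arrays of the 36 chemicals (100%) were assigned to their own chemical. Permuted labels gave a mean of 16.48 and at most 37 right in 1000 draws, and the permutation p of 0.001 is the smallest they can give. Since the arrays of a chemical may share handling, this does not separate chemical from batch. A chemical left out of the training was assigned to metal or not correctly in 9 of 13 cases (69.2%), with 7 of 9 metals and 2 of the 4 others right. Selenium, Zinc, Acrylonitrile and MTBE were assigned wrongly. The exact one-sided permutation p over all splits of the 13 chemicals was 0.231, which does not pass the threshold.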

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

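All tests of the ratios shared by the chemicals of a control were chosen after the result was seen, and the tests of similarity and the other splits were chosen before.

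The log2 ratios of the 13 Media chemicals moved together, with a median covariance across probes of 0.89 between chemicals. Sampling noise of 4 shared control arrays gave only 0.0402 in simulated unchanged chemicals, and a response common to all exposures cannot be the whole cause, since the mean ratios of Acetone and Media correlated at -0.286. Lack of a solvent in Media would move the treated arrays with the reference, and a shift of equal size in both would cancel in the ratio. The slope of the treated on the reference deviation from the other vehicles was 0.166, with r = 0.567 and SDs of 0.393 and 1.343. The reference is implied from the ratio, so large ratios by themselves lower this slope, and it does not decide on the lack of a solvent. The Media mean ratio correlated at 0.91 with minus the reference deviation, but the reference is implied from the ratio, which largely fixes that value, so it decides nothing. Control arrays handled apart and a true difference between control and exposed animals cannot be told apart, because the control arrays match no sample and were not used here.

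Some chemicals of unrelated class resembled each other, such as Beta-estradiol and Bifenthrin (r = 0.771 across probes within Ethanol) and 20 hydroxyecdysone and Selenium (0.642 within Media). Similarity fell with the difference in array brightness: r = -0.308 and rho = -0.328 over 78 Media pairs (one-sided permutation p = 0.0111 and 0.0102, adjusted 0.0222, r = -0.43 without the 2 farthest), and r = -0.202 and rho = -0.217 over 105 Ethanol pairs (p = 0.0232 and 0.0196, adjusted 0.0232, r = -0.268 without them), with 2 vehicles tested. The Ethanol value lies between the bounds set in advance and brightness is not independent of the chemical, so it cannot be told apart from a response. Chemicals of the same class were more similar by 0.079 (57 pairs at -0.015 ± 0.335 against 126 at -0.094 ± 0.262, one-sided permutation p = 0.0296), although 36 of the 57 are pairs of metals, and 7 of the 10 most similar pairs share a class, so shared class may add to the similarity without accounting for pairs of unrelated class. The moulting or reproductive stage of the animals stays open, as it is not given in the sources used here.

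Other splits of the same arrays were counted for 8 chemicals against the others of their vehicle, for the sum over 36 chemicals and for the pairs. They mix arrays of different chemicals, so arrays alike through a chemical or through shared handling make the real split the largest. They argue only against a random grouping of arrays and do not separate chemical from batch. Shares of 1 of 100 and 1 of 35 are the smallest that these splits can give. In 1 of 100 splits, the real one, as many probes set 20 hydroxyecdysone apart from the others (9481, highest other 2922), and the same held for Phenol (7864 and 674), Selenium (6488 and 3110), Methoxychlor (8261 and 1618), Chloroform (8680 and 953), Trichloroethylene (7128 and 666), Methylfarnesoate (6056 and 79), Atrazine (4874 and 165) and the sum over 36 chemicals (225853 and 10459). For the pairs, 1 of 35 splits was as large for Bifenthrin and Lamda Cyhalothrin (3922, highest other 555), Diazinon and Parathion (5372 and 2541), Chloroform and Trichloroethylene (7059 and 3331), 20 hydroxyecdysone and PonasteroneA (10498 and 8129) and Methylfarnesoate and Pyripoxyfen (7603 and 3591). For metals against other chemicals, 7 of 100 splits gave at least the real 1892 probes at an unadjusted p under 0.05, with 2953 at the highest, so chance cannot be excluded there.

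In some groups of 4 arrays, a single array lay apart from the other 3 relative to the range of the group, in several cases by a small distance. This was tested in 36 groups for the mean correlation with the other arrays, on values centred within the vehicle, and in 98 groups for named probes, and chance alone gives about 1 in 20. For named probes the items found were no more than this rate gives. The mean correlations of a group share pairwise values, so the rate does not strictly hold for them. Acrylonitrile replicate 1 had a mean correlation of 0.384 (others 0.656 to 0.671). Nickel replicate 3 had 0.668 (0.876 to 0.879). Methylfarnesoate replicate 3 had 0.729 (0.765 to 0.772). Chlorpyrifos replicate 4 had 0.845 (0.865 to 0.867). PonasteroneA replicate 1 had 0.917 (0.944 to 0.948). Phenanthrene replicate 1 had 0.932 (0.938 to 0.940). Permethrin replicate 2 had 0.946 (0.954 to 0.955). The log2 ratio of DM08360 in Methylfarnesoate replicate 4 was 10.50 (10.24 to 10.26). The log2 ratio of DM05344 in Methylfarnesoate replicate 2 was -5.98 (-2.58 to -2.24). The scanner log2 value of DM12463 in Selenium replicate 4 was 7.55 (8.40 to 8.55). The scanner log2 value of DM04057 in Lamda Cyhalothrin replicate 1 was 6.57 (6.60 to 6.61).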

How the results depend on the processing

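The settings without Acrylonitrile replicate 1, without Nickel replicate 3, without PonasteroneA replicate 1, with centring on the training chemicals and with the random block alone were chosen after seeing the data. No named probe changed direction or lost its call in 894 alternatives. These probes were named for their large changes in the same data, so this was nearly fixed in advance. In 64 of the 894, the minimum change of 1 on the log2 scale, the values were the same by construction. Of the leading results, 256 alternatives stayed within 1.5 times or on the same side of the threshold. Requiring a change of 1 on the log2 scale left 85492 calls against the control (20 hydroxyecdysone 5579, Phenol 4995, Selenium 4415, Methoxychlor 3153, Chloroform 2803, Trichloroethylene 2511, Atrazine 2300, Methylfarnesoate 1850) and 17231 against the other chemicals (in the same order 1148, 489, 472, 739, 885, 464, 234 and 607), as fewer probes can pass by construction. Atrazine had 8545 calls against the control and 4874 against the others, Selenium 10098 and 6488. Median centring gave 10009 for Atrazine against the others and 1669 for Bifenthrin and Lamda Cyhalothrin, and a fit on the 8 arrays gave 6362 for that pair, and the cause was not tested. For metals, leaving out replicates gave 0 to 2 calls, with 4 without Acrylonitrile replicate 1 and 0 without Nickel replicate 3 (smallest adjusted p from 0.0466 to 0.314 over these and the other scalings), and the chemical as a random block gave 573 with a replicate block and 616 without it, in fits whose degrees of freedom count arrays and not chemicals (consensus correlations 0.665 and 0.664). The totals without Acrylonitrile replicate 1 were 294306 and 227651. Of single chemicals outside the leading results, 579 alternatives stayed within 1.5 times and 97 did not, among them 2-chloro vinyl ether against the control with 1981 without replicate 1 and 7824 with quantile normalization of the ratios, and Toluene with 7815 in the latter. The replicate number as a block gave totals of 293018 and 225822. Not run were scanner values and normexp for the control comparison, since control arrays were not used here, and the gene list and marker tests. Signal over background limits the fold of dim probes.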

Other observations

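The swap test, the correlations of single arrays and the count without PonasteroneA replicate 1 were chosen only after the result was seen. The tests of a shift towards 20 hydroxyecdysone followed an unplanned look at the arrays.

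Over the scanner values of all 36 chemicals, 1060 of 14222 probes had chemical means that span over 3 log2 units and 258 over 5. DM04369 spanned 9.42, from 6.09 in Trichloroethylene to 15.51 in Beta-estradiol, with a within-chemical SD of 0.95. DM07343, named after its values were seen, spanned 9.15, from 6.14 in Diazinon to 15.29 in Nickel, with an SD of 0.5.

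On plainly subtracted values, PonasteroneA replicate 1 correlated with the 20 hydroxyecdysone arrays at 0.37 to 0.46 and with its own group at 0.17 to 0.21, and it was asked whether it lay between the groups. After normexp and quantile normalization, likewise centred on all arrays, it correlated with its own group at 0.92 to 0.93 and with 20 hydroxyecdysone at 0.25 to 0.30, where replicates 2 to 4 had 0.25 to 0.34, so the pattern was not there. A swap would leave a 20 hydroxyecdysone array out of place, and the lowest mean correlation within that group was 0.972. Mixed material or a response in a single beaker would move the array towards 20 hydroxyecdysone, and it covered -1.42% of the gap in 50 probes far higher there and -1.89% in 39 far lower, with up to 2.53% in the other arrays. The ratio of these shares, on which the predictions rested, has no meaning without a shift. The count for 20 hydroxyecdysone against PonasteroneA was 10350 without the array.

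On values centred on all arrays in place of those of the vehicle, Acrylonitrile replicate 1 correlated with its own group at 0.34 to 0.47 and with Trichloroethylene at 0.30 to 0.38, where replicates 2 to 4 had -0.03 to 0.05. Nickel replicate 3 correlated with its own group at 0.77 to 0.78 on the same values. Of the 857 probes that are not in the deposited value table, 62 were above background on all 4 arrays of a chemical and 64 on 0 arrays.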
